A study of Mus musculus with 135 samples.

How the data were processed

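RNA was measured by Smart-seq2 RNA sequencing in 107 of the 135 samples of the series: mouse oocytes, early embryos, parthenotes (embryos activated without sperm) and embryonic stem cells (ESCs). The other 28 samples come from chromatin and RNA polymerase II assays and genome sequencing and were not analysed here. The values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of each library), computed and deposited by the authors in 7 tables of genes by libraries. The submitters' processing notes name Trim Galore 0.6.6, HISAT2 2.2.1, StringTie 2.1.2, Bowtie2 2.3.5, deepTools 3.3.1 and Picard, and the genome build mm9. They do not tie each tool to a file.

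FPKM is a share of each library. Where a few transcripts take more of a library, all other genes read lower. The FPKM sums of the libraries ran from 37752 to 535770, and the share taken by Rn45s, the 45S ribosomal RNA precursor, ran from 0.114% to 71.5%. The tables do not give read counts. In 100 libraries, the most common ratio between low values held 0.767% to 11.1% of them, so whole reads could not be recovered. The depth of each library is therefore unknown, and no counting interval was computed. Many genes are listed at exactly 0, which in an FPKM table can be a failed estimate as well as an absence of reads. Such genes are described as listed at 0.

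Each table holds 24143 gene names, of which 27 that a spreadsheet had turned into dates were left out. Entries with the same gene name were summed. The tables were treated as separately normalized, and every test compared libraries of the same table. Group and replicate number were taken from the sample titles. The files hold 66 Obox genes. Obox, Zscan4, Usp17l, Tdpoz and Duxbl genes and predicted genes of the Eif1a type have near-identical copies, so reads may be split between copies, and values of single copies are uncertain.

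Choices of test, filter, threshold, gene lists and named genes were made before the data were examined, except where stated. A model was fitted with limma 3.58.1 in R 4.3.3 (tables read with data.table, version 1.17.8) to log2(FPKM + 1), on all replicated groups of a table together, followed by empirical Bayes moderation with a trend and robust variances. Genes with FPKM of at least 1 in at least 2 fitted libraries were tested. A gene was called where its Benjamini-Hochberg adjusted p was under 0.05 and its log2 fold change was at least 1 in size. "Rose" and "fell" are used for called genes and called lists. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The residual degrees of freedom were 16 (mzKO), 2 (mKO), 9 (Obox--), 11 (knockdown), 10 (ESC overexpression) and 6 (Nr5a2). There were 23 comparisons of a pair of groups and 3 contrasts of contrasts. The p-values measure only the spread between libraries, over all groups of a fit. Labels do not tell collections or cultures apart.

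There were 19 gene lists written before the data were examined: the Obox family, 2-cell genes of the MERVL era (genes switched on briefly around the 2-cell stage, many driven by the endogenous retrovirus MERVL), nucleolar and ribosome biogenesis genes, cytosolic ribosomal proteins, proteasome subunits, splicing factors, oxidative phosphorylation, mitochondrially encoded genes, oocyte and maternal genes, pluripotency, trophectoderm, primitive endoderm, early mesoderm and ectoderm, germ cell (meiotic and piRNA) genes, p53 targets, stress response, cumulus and granulosa cells, fibroblasts (feeder cells), and sperm and spermatid genes. The mitochondrially encoded list had 0 members in the files, which left 18 lists. Another 4 lists were made from these data by rules fixed beforehand: activated genes (1778, higher in wild-type late 2-cell embryos than in MII oocytes by at least 2 on the log2 scale), lost genes (1084, lower by as much), mzKO-down genes (1479) and mzKO-up genes (662), called between mzKO and wild-type late 2-cell embryos. Obox genes were left out of these 4 lists, and mean FPKM of at least 5 in the higher group was needed for the activated and lost lists. Lists were tested with camera at a preset inter-gene correlation of 0.01, again with the correlation estimated from the data, and with fry. Adjustment was over the lists of a comparison. Counts of called members come from the test over all genes, and counts "adjusted over the list alone" from an adjustment within the list.

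The genes named in the text follow a rule written before the data were examined. It takes all Obox genes. It also takes the called genes with mean FPKM of at least 5 in the higher group whose libraries do not overlap between groups, leaving out predicted and unnamed genes. Of these, the 10 with the largest change each way are taken in the 5 primary comparisons and 4 each way in the others. The primary comparisons are mzKO against wild type at the early 2-cell, late 2-cell and 4-cell times, and Obox3 and Obox5 against GFP in ESCs. In the primary comparisons it further takes up to 2 called members of each list each way. Nr5a2 is taken in the Nr5a2 knockout libraries, and 4 genes each way in unreplicated libraries. For contrasts of contrasts, overlap was judged on the first pair of groups. A few genes that the rule takes are not described. Genes outside the rule are said to have been chosen after their values were seen.

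The steps were tested in 5 simulations per comparison, with 200 genes changed in each. For mzKO against wild type, 0.896%, 22.7% and 70% of genes changed by 1, 2 and 3 on the log2 scale were called at the early 2-cell stage, and 4.78%, 50.4% and 93% at the late 2-cell stage. The shares were 10.1%, 83.9% and 98.8% for mKO, 31.9%, 98.8% and 99.7% for late Obox-- embryos, and 2.69%, 34.9% and 87% for siObox5. They were 1.19%, 21.2% and 69.7% for siObox4, 2.39%, 35.2% and 86.1% for siObox8, 10.7%, 86% and 98.5% for Obox3 in ESCs, and 3.88%, 64.5% and 96.4% for Obox3 in the Nr5a2 wild-type ESCs. Of simulated calls 4.24% to 8.83% were false. Real shares may be higher: other splits of ESC libraries gave up to 1442 calls. Changes of 1, the threshold, were mostly missed.

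Replicate numbers were not used in the fit. A pairing by number was shown in the ESC overexpression table alone. There, deviations of same-numbered libraries from their group means correlated. The lowest r was 0.276 for Obox3 and GFP, 0.414 for Obox5 and GFP and 0.213 for Obox3 and Obox5. With 2 libraries in a group a pairing cannot be told from the numbers. The labels do not say what the numbers share. For groups with 1 library, values and differences are given without a test, and the median of a list is placed as a percentile among 10000 random lists of the same size matched on mean expression. Libraries were also placed on an axis between a pair of groups. A gene's place is its log2 value scaled so that 0 is the mean of one group and 1 the mean of the other, a library being left out of its own group's mean, and the library's place is the median over the genes called between the groups. The alternatives tried were a pseudocount of 0.1, no filter on low values, median-of-ratios scaling of the libraries, the replicate number as a block, fits on the compared groups alone, an estimated inter-gene correlation, and leaving out each library in turn. Others, added after the data were seen, are described where they are given.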

Results

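Full-grown oocytes labelled Obox knockout held almost none of the 4 abundant maternal Obox transcripts, which encode homeobox transcription factors. Obox1 was at 0.11 ± 0.156 FPKM (SD, n = 2) against 1770 ± 463 (SD, n = 2) in wild-type oocytes. Obox2 was at 0.121 ± 0.172 against 2500 ± 436, Obox5 at 0.51 ± 0.721 against 2130 ± 143 and Obox7 at 0.0218 ± 0.0309 against 622 ± 44.2. OboxA10 (-4.28), OboxA11 (-3.96), OboxA5 (-3.68), OboxA7 (-3.96) and OboxA8 (-3.37) fell as well. Obox3 was listed at 0 in both knockout libraries and at 7.44 ± 3.53 in wild type, but was not called (adjusted p = 1). Beyond the Obox genes, Add3, an actin-capping adducin named here only after its values were seen, rose from 0.148 to 3.45, a call lost with any 1 library left out, and limma called 0 falls (53 of all genes tested had an unadjusted p under 0.05). The log2 fold changes of Obox1, Obox2, Obox5 and Obox7 were -10.62, -11.12, -10.55 and -9.25 (limma adjusted p = 1.41e-16 for Obox1), and 1 gene rose and 9 fell in total. The lists fixed beforehand did not move apart from the Obox family.

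In metaphase II (MII) oocytes Obox1, Obox2, Obox5 and Obox7 were listed at 0 in both knockout libraries and stood at 1770 ± 177, 2800 ± 232, 2550 ± 509 and 566 ± 83.2 FPKM (SD, n = 2) in wild type. OboxA5, OboxA7, OboxA10 and OboxA11 made up the rest of the 8 genes that fell, and none rose. The Obox family fell by 5.55 in the median (adjusted p = 1.93e-09 with an estimated correlation). Cytosolic ribosomal protein genes were higher by 0.61 in the median with 0 members called, and their rise (adjusted p = 1.26e-16) was lost with an estimated correlation (adjusted p = 0.991). So were those of proteasome, oxidative phosphorylation and activated genes and the fall of lost genes (0.991 each), none of them called in full-grown oocytes. Limma called 0 genes outside the family (159 of 13989 with an unadjusted p under 0.05). Such counts, also in full-grown oocytes and early mzKO embryos, are below chance, so little change is not shown.

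In early 2-cell embryos labelled mzKO (maternal and zygotic knockout), Obox1 was at 0.0918 ± 0.0721 FPKM (SD, n = 2) against 692 ± 203 in wild type (SD, n = 2). Obox2 was at 0.0954 ± 0.135 against 399 ± 140, Obox5 at 0.233 ± 0.301 against 1250 ± 119 and Obox7 at 0.0438 ± 0.00475 against 174 ± 108. Obox3 was listed at 0 in both mzKO libraries and at 20.2 and 53.5 in wild type (adjusted p = 0.0094), and Obox4 was at 0.0785 ± 0.111 against 179 and 24.3 (adjusted p = 2.92e-06). Obox6 (1.93 ± 1.56 against 13.3 ± 12.6, adjusted p = 1) and Obox8 were not called. Of the 56 genes that fell, 37 were Obox genes, and limma called 0 rises (331 genes had an unadjusted p under 0.05).

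Of the other 19 genes that fell at the early 2-cell stage, 16 are on the list of activated genes. Zfp352, a zinc finger gene transcribed around the 2-cell stage, fell from 172 ± 91.7 FPKM (SD, n = 2) to 6.26 ± 2.77 (SD, n = 2; log2 fold change -4.52, adjusted p = 0.017). Zfp54, another zinc finger gene, fell from 27.1 ± 28.4 to 0.28 ± 0.106 (-3.95), Guca1a, a guanylate cyclase activator, from 32.2 ± 31.6 to 0.727 ± 0.622 (-3.88) and Ddit4l, an mTOR inhibitor, from 26.2 ± 25.7 to 1.06 ± 0.975 (-3.38). D17Ertd648e fell from 7.7 ± 2.93 to 0.00438, and Olfr376, an olfactory receptor gene, was listed at 0 in both mzKO libraries against 20.5 ± 22.3. Among the predicted genes, Gm11517 (83.3 ± 6.52 to 0.365 ± 0.0195, -5.95), Gm10662 (-5.79) and Gm4567 (-5.65) fell most, and Gm5039 fell by 3.08. The 2-cell genes of the MERVL era fell as a list, with a median of -1.53 relative to all genes (adjusted p = 1.63e-30, and 0.0703 with an estimated correlation), 1 of 42 members called, and 16 down and 2 up when adjusted over the list alone. The mzKO-down genes were at -0.26 and the activated genes at -0.24 relative to all genes (0.913 for both with an estimated correlation), and the lost and mzKO-up genes at 0.21 and 0.23 (0.975 for both). Cytosolic ribosomal proteins were at -0.21 relative to all genes (0.975 with an estimated correlation), and their own median turned from 0.007 to -0.439 under scaling. Scaling shifted the median of all genes by -0.196, and the counts became 3 up and 103 down. The wild-type libraries differ from each other, and the second holds fewer detected genes (5539).

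**Figure D1:**
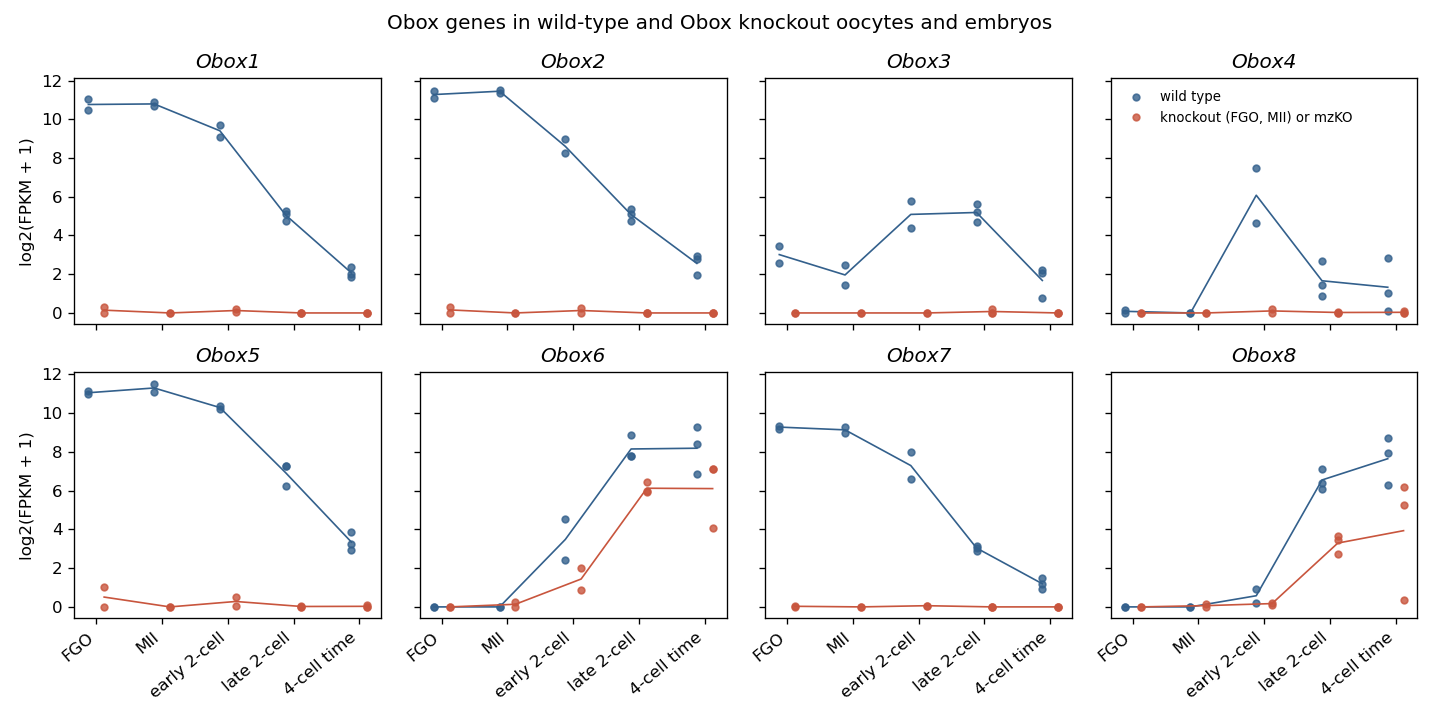
Obox1 to Obox8 in wild-type (blue) and knockout or mzKO (red) oocytes and embryos, as log2(FPKM + 1). Points are libraries and lines join group means.

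By the late 2-cell stage, Obox1, Obox2 and Obox7 were listed at 0 in all 3 mzKO libraries, and in wild type were at 32.6 ± 5.77, 33.3 ± 7.44 and 7.24 ± 0.756 FPKM (SD, n = 3). Obox3 fell from 36.7 ± 11.8 to 0.0562 ± 0.0974 (SD, n = 3 each; -5.11) and Obox5 from 127 ± 46.3 to 0.0153 ± 0.0265 (-6.91). Obox6 and Obox8 fell only in part, from 304 ± 145 to 69.9 ± 15.3 (-2.03, adjusted p = 0.0346) and from 97.5 ± 38.1 to 9.18 ± 3.1 (-3.26, adjusted p = 0.0103). Obox4 fell by 1.64 (adjusted p = 0.0404), and OboxB22 rose by 2.35.

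Obox, Gm and Rik genes aside, Spic, an ETS-family transcription factor, fell most at the late 2-cell stage, from 171 ± 118 FPKM (SD, n = 3) to 1.18 ± 0.53 (SD, n = 3; -6.11, adjusted p = 1.75e-06). Rnf11, a ubiquitin ligase, fell from 98 ± 28.2 to 1.41 ± 1.01, Pramel4 from 45.9 ± 15.4 to 0.329 ± 0.487 (-5.14), Npl, a sialic acid lyase, from 159 ± 115 to 3.08 ± 1.51 (-5.13) and Ccnb1ip1 from 57 ± 11.4 to 1.51 ± 0.916 (-4.57). Alppl2, an alkaline phosphatase, fell from 319 ± 106 to 13.4 ± 7.51, Sfi1, a centrosomal gene, from 27.9 ± 7.79 to 0.737 ± 0.243 and Rpusd3, a mitochondrial pseudouridine synthase, from 23.2 ± 14.2 to 0.391 ± 0.492. Ssr2, of the translocon complex, fell from 108 ± 27.2 to 5.65 ± 0.608 and Slc19a3, a thiamine transporter, from 65.1 ± 14.1 to 3.62 ± 2.7. Urah rose from 0.617 ± 0.32 to 37.7 ± 29.1 (4.31, adjusted p = 6.32e-08), S100a10 from 0.881 ± 1.02 to 30 ± 9.57 (4.15) and its partner Anxa2, a membrane-binding annexin, from 1.92 ± 1.5 to 31 ± 8.94 (3.57). Vim, the vimentin gene, rose from 0.356 ± 0.129 to 13.9 ± 0.812, Dmkn from 0.26 ± 0.411 to 15 ± 5.66, Mdk, a growth factor, from 0.429 ± 0.432 to 14.7 ± 6.21, Bex2 from 1.85 ± 1.7 to 26.5 ± 10.7, Rln1 from 0.566 ± 0.161 to 15.4 ± 3.98 and Osr2 from 5.53 ± 2.39 to 65.5 ± 30.3. Npy, a neuropeptide gene, was listed at 0 in wild type and stood at 10.2 ± 3.45 in mzKO embryos. In total 663 genes rose and 1502 fell in late 2-cell embryos. Without WT_L2C replicate 1 the count was 1321 (366 up, 955 down), and without mzKO_L2C replicate 3 it was 1435 (394 up, 1041 down).

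Nucleolar and ribosome biogenesis genes had 25 of 51 members down and none up at the late 2-cell stage. Polr1e, an RNA polymerase I subunit, fell from 36.9 ± 8.91 FPKM (SD, n = 3) to 2.32 ± 0.745 (SD, n = 3; -3.51) and Nob1, which trims the small ribosomal subunit RNA, from 71.5 ± 11.9 to 13.1 ± 1.82. The list's median change was -1.39 (adjusted p = 1.53e-10, and 0.519 with an estimated correlation). Cytosolic ribosomal proteins fell with it (11 of 81 members, median -1.18, adjusted p = 4.5e-08, and 0.622 with an estimated correlation), with Rpl7 at 31.1 ± 19.5 against 161 ± 58.2 and Rpl9 at 42.3 ± 20.8 against 196 ± 51.4. Psma6 (215 ± 88.2 to 41.2 ± 34.3) was among 5 of 32 proteasome subunits down (median -0.81, 0.659 with an estimated correlation), and 5 of 78 oxidative phosphorylation genes fell (median -0.52, 0.73 with an estimated correlation). The splicing factors had 0 of 44 called by limma (median -0.50, adjusted p = 0.0602).

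Oocyte and maternal genes stayed higher in late 2-cell mzKO embryos (4 of 58 up and 1 down, median 0.43, adjusted p = 0.00552, and 0.622 with an estimated correlation). Bmp15, an oocyte growth factor, was at 512 ± 238 FPKM (SD, n = 3) against 166 ± 64.6, and Wee2, a kinase that holds the oocyte in meiosis, at 225 ± 39.5 against 76.2 ± 25, while Zar1l fell from 10.4 ± 2.11 to 3.21 ± 0.549. Lost genes, cleared in wild type after MII, had 98 of 1084 members up and 4 down (0.622 with an estimated correlation), with Crabp2 (5.89 ± 2.53 to 70.6 ± 47.2) up and Mknk1 (13.2 ± 3.22 to 2.43 ± 1.85) down. Activated genes had 685 of 1778 down and 35 up (median -1.09, 0.346 with an estimated correlation), so much of the set that wild-type embryos switch on did not reach its level. In that list Gm11517 fell from 656 ± 86 to 5.87 ± 3.21 and Tmsb15b1 rose from 21.9 ± 4.08 to 122 ± 16.7. The list was chosen on these wild-type embryos and is not independent of this comparison.

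Lineage genes changed in both directions at the late 2-cell stage. In the pluripotency list (2 of 28 up and 6 down, adjusted p = 0.18), Fgf4, a growth factor, fell from 9.91 ± 4.96 FPKM (SD, n = 3) to 0.176 ± 0.305 and Fbxo15 from 493 ± 37.1 to 66.5 ± 5.61, while Klf4 rose from 6.4 ± 1.52 to 24.6 ± 7.13. Trophectoderm genes rose as a list (7 of 30 up and 1 down, median 0.37, adjusted p = 0.0126, and 0.622 with an estimated correlation), with Krt18 from 0.098 ± 0.114 to 6.09 ± 2.98 and Lgals3 from 10.6 ± 4.27 to 54.3 ± 16.9. Tead4, needed for that lineage, fell instead, from 6.09 ± 2.09 to 0.52 ± 0.434. Gata4 fell from 17.1 ± 2.18 to 4.4 ± 1.56 and Afp rose by 1.35 (primitive endoderm list, 0.077), Mixl1 fell from 6.38 ± 2.76 to 0.259 ± 0.248 and Eomes rose by 1.81 (early mesoderm and ectoderm list, 0.0586), and among germ cell genes (0.0602) Dazl rose from 24.2 ± 9.42 to 105 ± 12.6 and Dpep3 fell by 1.57.

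Among p53 targets at the late 2-cell stage (4 of 19 up and 1 down, adjusted p = 0.352), Btg2 rose from 3.73 ± 1.61 FPKM (SD, n = 3) to 18.9 ± 2.49 and Plk2 from 2.29 ± 1.15 to 13.1 ± 2.37, while Ei24 fell from 38 ± 12.5 to 10.2 ± 3.54. Ier2, from the stress response list (0.234), rose by 1.86, and Amhr2 fell from 15.9 ± 3.5 to 1.14 ± 1.53 in the cumulus and granulosa list (0.698). The fibroblast list, with Vim as its called member, rose by 0.49 (adjusted p = 0.0254, and 0.432 with an estimated correlation), and Ldhc fell by 2.58 in the sperm list (0.256). The 2-cell genes were split at this stage, 13 of 42 up and 7 down (median 0.55, adjusted p = 0.154). Usp17le (1.65 ± 0.792 to 15.6 ± 8.45) and Usp17la (2.06 ± 1.63 to 13.2 ± 7.67) rose, while Ubtfl1 (59.9 ± 3.56 to 11.6 ± 3.19) and Sp110 (64.5 ± 4.18 to 13.1 ± 2.65) fell.

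**Figure D2:**
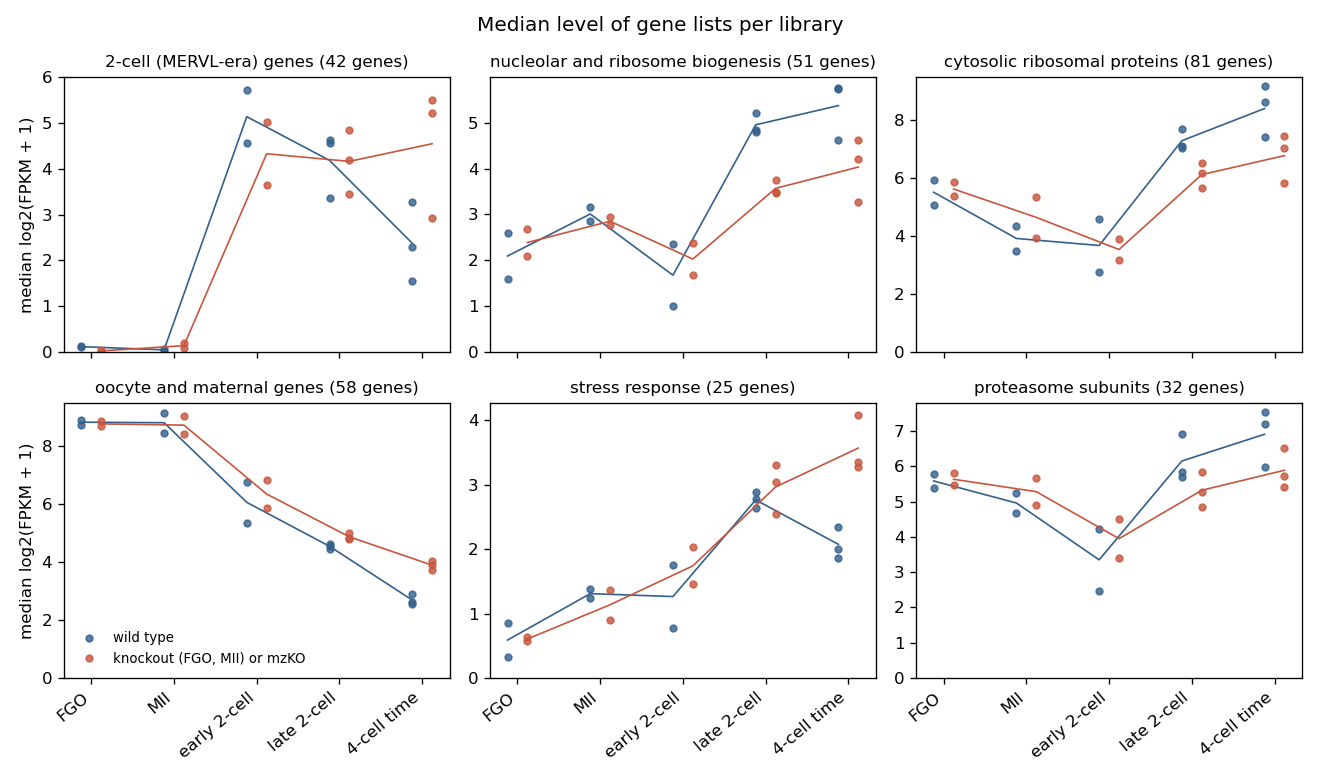
Median log2(FPKM + 1) of 6 gene lists per library from the full-grown oocyte to the 4-cell time, wild type in blue and knockout or mzKO in red. Lines join group means.

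At the time when controls were at the 4-cell stage, which the labels also give for the mzKO libraries, Obox1, Obox2, Obox3 and Obox7 were listed at 0 in all 3 mzKO libraries. In wild type they were at 3.24 ± 0.784, 5.13 ± 1.99, 2.49 ± 1.56 and 1.32 ± 0.48 FPKM (SD, n = 3). Obox5 fell from 9.51 ± 3.47 to 0.0212 ± 0.0367 (-3.31). Obox6 fell from 360 ± 254 to 98.2 ± 71.6 (-2.08, adjusted p = 0.0219) and Obox8 from 247 ± 169 to 36.6 ± 35.8 (-3.71, adjusted p = 0.00301), with the mzKO libraries far apart (139, 140 and 15.6 for Obox6, and 37.7, 71.8 and 0.272 for Obox8). Obox3 (adjusted p = 0.121) and Obox4 (adjusted p = 0.0799) were not called.

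The 2-cell genes, low by then in wild type, were high in mzKO embryos at the 4-cell time. BB287469, an Eif1a-like gene, rose from 4.64 ± 1.33 FPKM (SD, n = 3) to 504 ± 273 (SD, n = 3; 6.38, adjusted p = 2.64e-08), Usp17lc from 2.3 ± 1.14 to 91.1 ± 60.2 (4.54), Gm6763 from 2.29 ± 1.4 to 393 ± 352 and Gm4027 from 4.69 ± 1.41 to 427 ± 217. As a list, 23 of 42 rose and 2 fell, and the median was 1.86 above that of all genes (adjusted p = 1.05e-06, and 0.35 with an estimated correlation). Ubtfl1 (52.8 ± 20.9 to 8.86 ± 5.45) and Sp110 (87.6 ± 29.4 to 30.8 ± 30.6) went down here as before. Sva rose from 0.0872 ± 0.151 to 108 ± 91.1 (6.18), Irf1, an interferon-response factor, from 0.29 ± 0.266 to 43 ± 23.5 (4.98), Mdk from 0.153 ± 0.138 to 25.2 ± 6.99, Crabp2, a retinoic acid carrier, from 0.468 ± 0.28 to 31 ± 7.82 and Cd24a from 2.01 ± 0.818 to 70.2 ± 47.4. S100a10 rose from 1.16 ± 1.29 to 32.5 ± 4.13 and Rassf1 from 0.614 ± 0.144 to 32.1 ± 22, and Dmkn, listed at 0 in wild type, stood at 36.9 ± 0.8.

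At the 4-cell time Bhmt, of the methionine cycle, fell from 123 ± 89.2 FPKM (SD, n = 3) to 0.767 ± 0.845 (SD, n = 3; -5.82), Phgdh, of serine synthesis, from 134 ± 45.2 to 4.54 ± 3.81 (-4.80), and Gja1, a gap junction protein, from 49.4 ± 31.5 to 0.559 ± 0.503 (-4.81, adjusted p = 3.64e-09). Spic (277 ± 129 to 10.8 ± 16.8), Pramel4 (133 ± 38.7 to 2.6 ± 3.05), Npl (219 ± 76.6 to 9.71 ± 7.12) and Rnf11 (88.9 ± 8.02 to 3.25 ± 0.727) stayed low from the stage before. Timd2 (478 ± 187 to 35.7 ± 34.5), Nt5c3b (31.9 ± 16.6 to 0.631 ± 0.412) and Sycn (30.7 ± 20.2 to near 0) fell too. In all, 1990 genes rose and 1450 fell. Without WT_4C replicate 2 the count was 2129 (1365 up, 764 down), and without mzKO_4C replicate 3 it was 2159 (1290 up, 869 down). Without WT_4C replicate 3 falls outnumbered rises (1485 up, 1758 down), and with Rn45s left out 2716 rose and 908 fell.

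Ribosomal genes were low at the 4-cell time as well. Rpl3 fell from 316 ± 278 FPKM (SD, n = 3) to 47 ± 36.4, within 29 of 81 ribosomal proteins called (median -1.56 relative to all genes, adjusted p = 3.63e-15, and 0.35 with an estimated correlation). Nucleolar genes had 22 of 51 down (-1.34 relative to all genes, 0.35 with an estimated correlation), with Polr1e at 4.07 ± 2 against 35.2 ± 11.2 and Wdr12 at 3.13 ± 2.13 against 27.3 ± 14.9. Snrpa1 (67.3 ± 24.4 to 13.8 ± 8.65) was among 6 of 44 splicing factors down (0.395 with an estimated correlation) and Psma6 (366 ± 154 to 113 ± 57.6) among 3 proteasome subunits (0.505). Of the oxidative phosphorylation genes, Ndufb2 (187 ± 72.2 to 19.6 ± 9.75) was among 7 down and Cox7b (45.2 ± 21.7 to 115 ± 29.7) the 1 up (0.53 with an estimated correlation).

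Stress and maternal transcripts were the other marked gains at the 4-cell time. Ddit3, a factor of the unfolded protein response, rose from 3.3 ± 0.978 FPKM (SD, n = 3) to 44.1 ± 6.79 (3.40) and Hmox1, an oxidative stress gene, from 2.48 ± 1.87 to 24.4 ± 10.8, while the chaperone Hspa8 fell from 525 ± 306 to 142 ± 80.8. Of 25 stress genes 13 rose and 1 fell (median 1.06 above all genes, adjusted p = 0.000321, and 0.35 with an estimated correlation). Among p53 targets (7 up and 2 down, 0.508 with an estimated correlation), Btg2 rose from 0.823 ± 0.387 to 22.8 ± 10.4 and Ei24 fell from 59.4 ± 6.72 to 11.3 ± 3.1. Oocyte genes stayed up, with 27 of 58 called higher and 3 lower (1.12 above all genes, 0.35 with an estimated correlation). Bmp15 was at 73.8 ± 26.1 against 11.1 ± 6.79 and Wee2 at 44.6 ± 38.4 against 4.69 ± 1.25, but Dppa3, which guards maternal DNA methylation, fell from 2320 ± 672 to 309 ± 122. Lost genes had 258 members up and 25 down (0.53 with an estimated correlation), Fam151a (8.94 ± 3.76 to 0.414 ± 0.358) among the latter.

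Lineage genes remained split at the 4-cell time. Dppa5a fell from 510 ± 158 FPKM (SD, n = 3) to 41.1 ± 28.9 and Tdgf1 from 30.2 ± 24 to 2.88 ± 4.38 among 10 of the pluripotency genes, against 3 up with Klf4 (2.93 ± 1.43 to 11.5 ± 1.19), and the list fell (adjusted p = 0.00183, and 0.35 with an estimated correlation). Tead4 fell from 20.5 ± 6.31 to 0.731 ± 0.415 and Hand1 from 24.3 ± 18.1 to 1.87 ± 1.75, while Gata2 rose from 0.326 ± 0.379 to 13.2 ± 4.88 and Lgals3 from 6.83 ± 0.468 to 68.8 ± 23.2 (trophectoderm list, 0.0545). With estimated correlations, the primitive endoderm list (Afp up by 2.90, Gata6 down) had an adjusted p of 0.351, early mesoderm and ectoderm (Mesp2 up by 2.37, Mixl1 down) 0.35, germ cell genes (Dazl up, 5.89 ± 2.31 to 73.5 ± 61.6, among 7) 0.508 and fibroblast genes (Vim up by 2.91) 0.35. In the cumulus list (0.435) Amhr2 fell by 1.73, and in the sperm list (0.712) Tssk6 rose by 1.60 and Ldhc fell by 1.84.

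The genes called at the late 2-cell stage mostly kept their direction at the 4-cell time, in embryos other than those that defined the lists. Of the 1479 mzKO-down genes 797 fell and 4 rose, Tbxa2r (1.58) among the latter. Of the 662 mzKO-up genes 366 rose and 1, Hmga2 (4.56 ± 3.43 FPKM to 1.09 ± 0.469, SD, n = 3), fell. With an estimated correlation the lists had adjusted p of 0.0692 and 0.183. Of the activated genes 551 fell, with Gm13102 (131 ± 41.1 to 1.73 ± 1.94) near the top, and 127 rose (0.35).

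The contrast between late and early 2-cell effects of mzKO, a comparison of comparisons, shows what was new at the late stage. Yipf1, a Golgi membrane gene, stood at 3.45 ± 1.18 FPKM (SD, n = 3) against 64.2 ± 29 in the late embryo, -4.18 relative to the change in the early embryo (adjusted p = 0.0102). Cog4, also of the Golgi (-4.17), Rpusd3 (-4.05) and Mrps10, of the mitochondrial ribosome (-3.96), behaved alike. S100a10 (4.15, adjusted p = 0.0119), Sva (3.92) and BB287469 (3.89) went the other way. Obox1, Obox2, Obox4, Obox5 and Obox7 had positive values (4.22, 3.40, 4.33, 3.10 and 4.20), since wild type had less of them left to lose. The 2-cell genes lost their early fall, 1.63 above all genes (8 up, 0 down, adjusted p = 3.69e-13, and 0.341 with an estimated correlation). Nucleolar genes fell, to -1.32 relative to all genes (0.492 with an estimated correlation).

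That contrast had 65 genes up (29 of them Obox genes) and 198 down, 56 and 64 after scaling, which shifted the median of all genes by 0.239 and moved the upward share from 24.7% to 46.7%. A pseudocount of 0.1 left 12 (2 up, 10 down). The count rests on single early libraries: without WT_E2C replicate 1 it was 476, without WT_E2C replicate 2 it was 91 (49 up, 42 down), without mzKO_E2C replicate 1 it was 62 and without mzKO_E2C replicate 2 it was 130. Without WT_L2C replicate 1 it was 153 and without mzKO_L2C replicate 3 it was 167.

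Embryos labelled mzKO_BL are arrested 2-cell embryos collected when controls were blastocysts. In them Obox3 was at 59.7 FPKM in the library labelled mzKO_BL replicate 1, against its label, and listed at 0 in replicate 2 and in both wild-type blastocysts. OboxA9 was at 9.58 in replicate 1, and both genes were called up on the strength of that library. Oocyte genes persisted: Npm2, a histone chaperone of the egg, was at 46.2 ± 17 FPKM (SD, n = 2) against 0.133 ± 0.188 (SD, n = 2) and Nlrp14 at 35.7 ± 37.7 against 0.0231 ± 0.0326. Esx1, a placental homeobox gene, was at 62.4 ± 56.2 against 0.0827 ± 0.117 and the heat shock gene Hspa1a at 56.6 ± 63.7 against 0.0751 ± 0.0402. Blastocyst genes were missing, with Mt1 at 4.27 ± 6.04 against 8930 ± 391, Gabarapl2 at 0.741 ± 1.05 against 2310 ± 167, Fabp3 at 3.59 ± 3.83 against 5600 ± 2850 and the epithelial keratin Krt8 at 0.334 ± 0.473 against 1330 ± 443.

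All 32 proteasome subunits, 80 ribosomal proteins and 75 oxidative phosphorylation genes were lower in arrested embryos than in blastocysts. Ribosomal proteins were at -6.55 relative to all genes (adjusted p = 2.55e-31) and oocyte genes at 2.38 (31 up and 5 down, adjusted p = 2.12e-20). The 2-cell genes were 0.95 above all genes (0.404 with an estimated correlation). Pluripotency genes (22 down, 0.239), trophectoderm genes (22 down, 0.205) and splicing factors (37 down, 0.339) were lower. The ribosomal, proteasome, oxidative phosphorylation and oocyte lists each had an adjusted p of 0.205 with an estimated correlation, nucleolar genes (41 down) 0.463 and stress genes (7 up and 10 down) 0.299. The median of all genes was at -0.949, and 416 genes rose and 6099 fell. Rn45s took 55.4% and 71.5% of the arrested libraries, whose FPKM sums were 74531 and 37752. Scaling shifted the median by 0.637, turned the stress genes from -0.242 to 2.175, and gave 2143 up and 4790 down (upward share 6.39% to 30.9%). With Rn45s left out, a check added after the data were seen, 3635 rose and 2953 fell, so the balance of rises and falls depends on the library totals. The arrested embryos also differ from blastocysts in stage.

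Single libraries come from mzKO embryos injected with Obox mRNA. The injected Obox1, Obox3, Obox4, Obox5 and Obox7 were listed at 0 by the time of collection, so the injection cannot be seen in these libraries. In the library labelled Obox157OE, a blastocyst by its label, Mt1 was at 9120 FPKM against 4.27 in arrested embryos labelled mzKO (of which replicate 1 held Obox3 at 59.7, against its label), Fabp3 at 5570 against 3.59 and Krt8 at 1710 against 0.334. Gadd45b (1.04 against 71.6), Esx1 (0 against 62.4), Npm2 (0.271 against 46.2) and Hspa1a (0 against 56.6) were low. The library labelled Obox3OE, also a blastocyst, had Mt1 at 11000, Rps27rt at 969 against 0.18 and Gstp1 at 860 against 0, with Gadd45b at 0.149, Npm2 and Esx1 at 0 and Hspa1a at 0.106. Ribosomal proteins were higher by 7.86 in the first and 7.38 in the second (percentile 100 among random lists for both), and oocyte genes lower (-1.64 and -1.80).

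The library labelled Obox4OE comes from arrested 2-cell embryos and differs. In it Mt1 (391 FPKM against 4.27) and Rps27rt (143 against 0.18) were higher, and Rnf141 (0.169 against 77), Esx1 (0.483 against 62.4), Npm2 (0.718 against 46.2) and Gdf9 (0.177 against 38.7), an oocyte growth factor, were lower. Here 2-cell genes were higher by 4.37, in 39 of 40 genes (percentile 100), ribosomal proteins by 4.46, and oocyte genes lower (-1.76, 46 of 49 genes). On the axis from arrested embryos (0) to blastocysts (1), over 6515 genes, the median place was 1.097 for Obox157OE, 0.876 for Obox3OE and 0.253 for Obox4OE, with wild-type blastocysts at 1.25 and 0.8 (SD 0.318). The place of Obox4OE moved to 0.716 under scaling and to 0.43 with a pseudocount of 0.1. Each is a single library without a test.

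**Figure D3:**
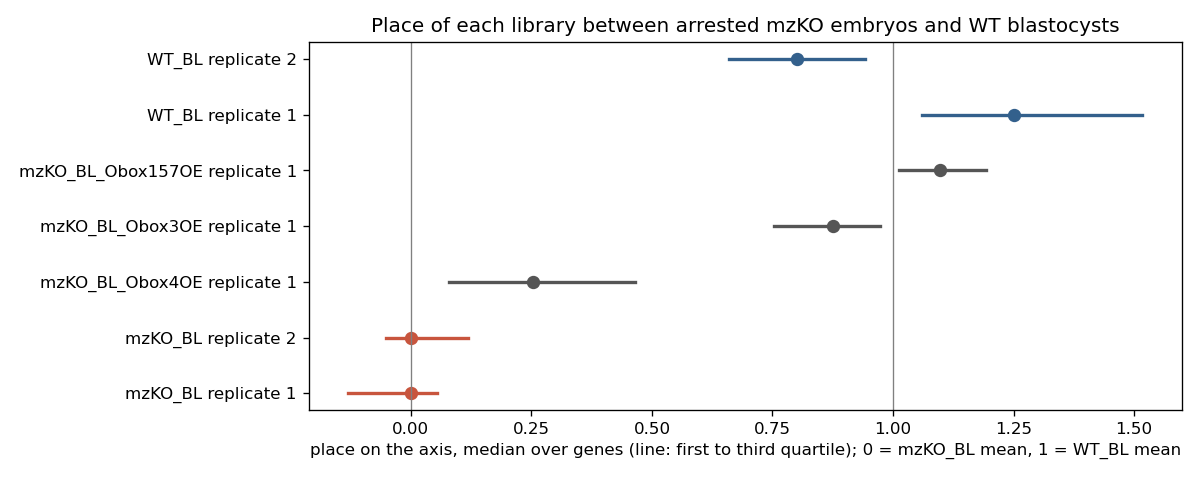
Median place of each library between arrested mzKO embryos (0) and wild-type blastocysts (1). Lines run from the first to the third quartile over genes.

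Late 2-cell embryos labelled mKO (maternal knockout) lacked the maternal Obox transcripts but kept zygotic ones. Obox1 was at 0.154 ± 0.109 FPKM (SD, n = 2) against 28.3 ± 13.5 (SD, n = 2), Obox5 at 0.445 ± 0.228 against 94.9 ± 51.4 and Obox7 at 0.229 ± 0.323 against 8.05 ± 4.34, and Obox2 was listed at 0 in both mKO libraries against 28.3 ± 14.7. Obox6 fell from 469 ± 15.5 to 172 ± 49.8 (adjusted p = 0.0498) and OboxA10 fell by 1.40. Obox3 was at 12.7 ± 2.4 against 27.3 ± 15.8 (adjusted p = 0.204), and Obox4 and Obox8 were not called.

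S100a10 rose in mKO as in mzKO embryos, from 0.319 ± 0.452 FPKM (SD, n = 2) to 31.1 ± 15.4 (4.56, adjusted p = 0.0173), as did Cd24a, from 2.04 ± 1.61 to 31.2 ± 2.53, Sva, from 5.08 ± 6.89 to 52 ± 24.7, and the Polycomb gene Phc2, from 2.94 ± 0.0666 to 44.2 ± 0.486. Among the falls, Ndufa12, of complex I, went from 86 ± 36.9 to 2.48 ± 2.64 (-4.82), Timm13, of the import machinery, from 57.8 ± 9.92 to 1.68 ± 1.53 and Mrpl33 from 52.3 ± 14.7 to 2.53 ± 1.14. MERVL-era 2-cell genes were 2.22 above all genes (10 of 40 up, none down, adjusted p = 1.23e-18, and 0.414 with an estimated correlation). Proteasome subunits (20 of 32 down) and oxidative phosphorylation genes (29 of 77 down) were at -1.14 and -0.73 relative to all genes (0.414 with an estimated correlation for both). Nucleolar genes (9 of 50 down, 0.414), ribosomal proteins (12 of 81 down, 0.618) and 8 splicing factors were down too. The lost genes stood 0.27 above all genes (0.617 with an estimated correlation; own median -0.212, and 0.263 after scaling), and 407 activated genes fell and 25 rose (0.414).

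Of the 1430 mzKO-down genes measured in the mKO table, 372 fell and none rose (-0.58 relative to all genes, adjusted p = 7.37e-12, and 0.414 with an estimated correlation). Of 474 mzKO-up genes 46 rose and 4 fell (0.92 above, and 0.414). The 372 shared falls compare with 164 under independence, and 46 shared rises with 6.39. The comparison as a whole had 149 up and 1182 down of 10341 genes, and the median of all genes was at -0.48. After scaling, which shifted it by 0.492, limma called 0 genes, although the genes called down kept a median of -1.316 (-1.825 before) and the smallest adjusted p was 0.0517. Without mKO_L2C replicate 1 the count was 2940, without mKO_L2C replicate 2 it was 2231, without the wild-type library replicate 1 it was 134 and without replicate 2 it was 15. A single mKO blastocyst library differed from its control in few genes, 19 higher and 20 lower by at least 2 on the log2 scale. Pdcd4 (49.5 FPKM against 6.41) and Alpl (50.6 against 7.02) were higher, and Chac1 (0.299 against 17.6) and Trib3 (7.14 against 67.9) lower. Ribosomal proteins were lower (-0.443, 78 of 80 genes, percentile 0) and pluripotency genes higher by 0.416 (23 of 27, percentile 99.96).

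Embryos labelled Obox-- were compared with Obox+- embryos. At the early 2-cell stage Obox3 was listed at 0 in all 3 Obox-- libraries against 7.8 ± 2.72 FPKM (SD, n = 3), and Obox4 at 0 against 3.04 ± 0.504. Obox1 (101 ± 4.24 against 56.6 ± 4.92, adjusted p = 0.244) and Obox5 (347 ± 130 against 258 ± 16.3) were not lower, so maternal Obox transcripts were present. Fbxo15 fell from 91 ± 7.76 to 38.5 ± 7.44 (-1.24, adjusted p = 0.0128), Vimp from 20.7 ± 3.06 to 5.95 ± 2.25 and Lars2 from 281 ± 74.5 to 119 ± 18.5. Snora28 (0.495 ± 0.546 to 5.89 ± 3.05), the homeobox gene Nkx6-2 (0.937 ± 0.499 to 5.6 ± 3.09) and Dynlt1f (1.27 ± 0.0994 to 5.81 ± 0.342) rose. Relative to all genes, 2-cell genes were at -0.61 (0 of 39 called by limma, adjusted p = 4.42e-10, and 0.203 with an estimated correlation). The mzKO-down genes (0.561 with an estimated correlation) and the activated genes (0.574) were at -0.18 and -0.14, their own medians turning from 0.056 to -0.119 and from 0.101 to -0.147 under scaling. In total 14 genes rose and 40 fell, 25 of the latter Obox genes. Scaling shifted the median of all genes by -0.228 and gave 8 up and 56 down (upward share 25.9% to 12.5%).

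At the late 2-cell stage of the Obox-- embryos Obox3 was listed at 0 in all 4 libraries against 18 ± 8.01 FPKM (SD, n = 3; adjusted p = 6.73e-08). Obox4 was listed at 0 against 0.752 ± 1.04 and was not called, nor were Obox6 (190 ± 22.3 against 220 ± 39.9), Obox8 (105 ± 4.37 against 119 ± 40.2) and Obox5 (2.83 ± 2.26 against 4.21 ± 2.06). Spic fell from 352 ± 65.6 to 68.6 ± 57.9 (SD, n = 4; -2.70, adjusted p = 0.008), Gja1 from 11.6 ± 4.9 to 0.592 ± 0.448 (-2.94), Dppa5a from 206 ± 109 to 36.8 ± 27.3 (-2.56) and the ubiquitin ligase Siah1a from 16.1 ± 3.3 to 1.88 ± 1.58. Cldn6, a tight junction gene, rose from 1.93 ± 0.878 to 16.6 ± 4.97 (2.59), Fut8 from 0.177 ± 0.0637 to 5.38 ± 2.25 and Rhog from 1.49 ± 1.44 to 8.54 ± 4.15.

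Spic and Gja1 are thus shared with the mzKO embryos, and the mzKO-down list was at -0.27 relative to all genes (24 of 1385 down and 1 up, adjusted p = 4.85e-13, and 0.581 with an estimated correlation) in late Obox-- embryos. The mzKO-up list was 0.17 above (8 of 521 up, none down, 0.758 with an estimated correlation), and 24 shared falls and 8 shared rises compare with 4.49 and 1.23 under independence. Ribosomal proteins (0.758) and nucleolar genes (0.856) were at -0.27 and -0.23 relative to all genes, and oocyte genes (0.758) at 0.25. Counts were 27 up and 47 down, and 23 and 70 after scaling, which shifted the median by -0.106 (upward share 36.5% to 24.7%). Without Obox+-_L2C replicate 3 the count was 43 and without Obox--_L2C replicate 1 it was 132.

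Few genes besides the target were called with siRNA to single Obox genes. In late 2-cell parthenotes siObox12mix lowered Obox1 from 214 ± 149 FPKM (SD, n = 3) to 0.815 ± 0.25 (SD, n = 2; -6.68, adjusted p = 2.5e-06) and Obox2 from 87.1 ± 54.9 to 0.525 ± 0.743 (-5.77), with Obox5 not called (407 ± 415 against 601 ± 226, adjusted p = 1). Gsto2, a glutathione transferase, also fell, from 8.09 ± 1.02 to 0.909 ± 0.303, and no gene rose. siObox5 lowered Obox5 from 601 ± 226 to 5.8 ± 4.94 (-6.61, adjusted p = 3.7e-05), and OboxB22 (1.89) and Morc4 (1.81), named after their values were seen, rose. siObox7 lowered Obox7 from 23.8 ± 14.9 to 1.01 ± 0.852 (-3.51, adjusted p = 0.015), and no other gene was called. With siObox12mix 2-cell genes were higher by 0.343 (adjusted p = 0.513 with an estimated correlation), as were nucleolar genes by 0.329 (0.513) and ribosomal proteins by 0.315 (0.513), and oocyte genes were lower (-0.45, 0.326), all with 0 members called. The mzKO-down genes were higher by 0.183 (0.513), opposite to mzKO embryos. With siObox5 2-cell genes were higher by 0.396 (0.465) and the mzKO-down genes lower (-0.137, 0.938). For siObox7 none of 22 lists was called. Unadjusted p under 0.05 was found for 245, 255 and 117 of 12881 genes. This is below chance, as with siRNA in zygotes, so little change is not shown. The siObox5 count of 3 became 6 without siCtrl replicate 1 and 1 without siObox5 replicate 1 or siCtrl replicate 3. The single siObox7 call became 0 without siCtrl replicate 1, siCtrl replicate 2 or either siObox7 library.

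In embryos from zygotes injected with siRNA, the targets were low but not called in unpaired fits. Obox4 was at 7.05 ± 5.2 FPKM (SD, n = 2) against 44.5 ± 10.1 (adjusted p = 0.442) with siObox4 in early 2-cell embryos, Obox6 at 19.9 ± 9.42 against 328 ± 212 (SD, n = 3; adjusted p = 0.138) with siObox6 and Obox8 at 12.2 ± 12.7 against 134 ± 92.1 (adjusted p = 1) with siObox8 in 4-cell embryos. With siObox6, Rhox6, a reproductive homeobox gene, rose from 1.14 ± 1.01 to 8.18 ± 2.85 and Pop4, an RNase P subunit, fell from 77.7 ± 27.9 to 3.38 ± 0.557 (-4.10, adjusted p = 0.00723). With siObox4, Elmo1, named after its values were seen, fell by 1.67, and none of 22 lists was called. With siObox6 trophectoderm genes stood 0.70 above all genes (adjusted p = 2.83e-05, and 0.518 with an estimated correlation), oocyte genes at -0.27 (0.468) and 2-cell genes at -0.21 (0.985). With siObox8 limma called 0 genes, 207 had an unadjusted p under 0.05, and oxidative phosphorylation genes were lower (-0.431, 0.976 with an estimated correlation). For siObox6, 8 genes rose and 1 fell (546 with an unadjusted p under 0.05), and 5 and 1 after scaling, which shifted the median by -0.11. Without siObox6 replicate 2 the count was 49 (45 up, 4 down), without siCtrl replicate 1 it was 5 and without siCtrl replicate 3 it was 3. For siObox4 the single call was lost without any of the 4 libraries (130 genes with an unadjusted p under 0.05), and for siObox8 the count was 7 without siObox8 replicate 2 and 1 without siObox8 replicate 1 or siCtrl replicate 3.

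A single library with siObox3 in late 2-cell embryos had Obox3 at 19.6 FPKM against 113, along with lower Obox1 (15.6 against 119), Obox2 (17.6 against 91), Obox7 (4.49 against 23.6) and Obox6 (56.6 against 152), but not Obox5 (378 against 341). Ppp2r5c was higher (24.2 against 3.78), and Phc2 (1.32 against 18) and Srsf4 (0.22 against 6.39) lower. The mzKO-down genes were lower (-0.375, 1018 of 1263 genes, percentile 0), as were activated genes (-0.348). No test was run for this single library.

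Wild-type embryos injected with Obox mRNA were each compared with a water-injected library. At the late 2-cell stage Obox1 was at 533 FPKM against 12.9, Obox2 at 50.8 against 15.5, Obox3 at 71.8 against 39.9 and Obox5 at 68.2 against 37.7 in the libraries so labelled. With Obox1, Tagln2 was higher (26.5 against 2.95) and Timd2 (12 against 97.2) lower. The mzKO-down genes were lower with Obox1 (-0.715), Obox3 (-0.288) and Obox5 (-0.17, percentile 0 each) but higher with Obox2 (0.08, percentile 100). The Obox1 library had an FPKM sum of 132770 against 182213, Rn45s at 12.4% against 6.24%, and a median of all genes of -0.309. With Obox3, Tsga8 (31 against 2.33), S100a6 (14.5 against 0.813) and Dmkn (9.93 against 0.219) were higher, and trophectoderm genes higher by 0.69 (percentile 100). With Obox5, Tsga8 (30.7) and Dmkn (8.27) were higher, Tex101 lower (5.63 against 43.1), and 2-cell genes higher by 0.725 (36 of 39 genes, percentile 100). Few genes differed by at least 2 on the log2 scale: 20 higher and 102 lower with Obox1, 4 and 7 with Obox2, 23 and 9 with Obox3, and 19 and 9 with Obox5.

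Of the wild-type blastocyst libraries, the library labelled WT_BL_Obox1oe stood apart, with 253 genes higher and 736 lower than the water-injected library. BB287469 was at 296 FPKM against 0.111, Zscan4c, of a telomere-linked 2-cell family, at 153 against 0.0553, and Zscan4f at 238 against 0. Slc15a2 (2.25 against 244) and Tspan8 (7.7 against 432) were lower. The 2-cell genes were higher by 4.71 (39 of 41 genes, percentile 100), the Obox family by 2.70 with Obox4 at 44.7 against 0.12 and Obox6 at 45.6 against 6.92 but Obox1 at 3.37, and trophectoderm genes were lower (-2.09, percentile 0). Oocyte genes were not raised (-0.905, 5 of 16 genes higher, percentile 33.5), and 7917 genes were detected against 9142. Its FPKM sum was 241615 against 476238 and the median of all genes -0.869, so no effect of Obox1 can be stated. In the blastocyst libraries labelled Obox2oe (15 genes higher, 11 lower), Obox3oe (7 and 31) and Obox5oe (17 and 13) the named gene was near 0 (0.211, 0.135 and 0), so none can be stated either.

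In ESCs, overexpression brought Obox3 to 1630 ± 783 FPKM (SD, n = 4) against 7.44 ± 16.6 with GFP (SD, n = 5; 9.46, adjusted p = 0.000703) and Obox5 to 1250 ± 704 against 3.97 ± 8.54 (9.07, adjusted p = 0.00017). With Obox3, Guca1a, among the first genes lost in mzKO embryos, rose from 0.992 ± 0.938 to 367 ± 160 (7.53, adjusted p = 4.75e-09) and Trim43a from 0.137 ± 0.157 to 116 ± 50.7 (6.58). Fmo1, a monooxygenase, rose from 0.0248 ± 0.0555 to 37.3 ± 18.5, Pemt, of phosphatidylcholine synthesis, from 5.15 ± 2.89 to 193 ± 63.5 and Crxos, a homeobox gene, from 0.162 ± 0.164 to 27 ± 11.1. Aqp9 (0.449 ± 0.495 to 29.6 ± 12.3), Chit1 (0.394 ± 0.676 to 25.3 ± 5.71), Ninj2 (0.239 ± 0.302 to 25 ± 12.1), Bex6 (0.0134 ± 0.03 to 16.5 ± 1.25) and Klf17 (0.0671 ± 0.0914 to 13.4 ± 5.89), a Krüppel-like factor of early embryos, followed. Among the falls were the junction genes Cldn4 (26.7 ± 3.83 to 6.56 ± 3.26, -1.97), Ildr1 (11.7 ± 4.81 to 2.67 ± 1.03) and Gjb5 (27.9 ± 10 to 7.92 ± 3.22), then Tnfrsf21 (6.35 ± 3.42 to 1.63 ± 0.451) and Slc17a9 (11.5 ± 2.23 to 4.04 ± 1.66). In total 316 genes rose and 22 fell in Obox3 ESCs, 371 and 108 with the replicate number as a block, and 438 and 69 after scaling.

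The 2-cell genes rose in Obox3 ESCs, 15 of 33 with none down (median 1.91, adjusted p = 2.56e-26, and 0.211 with an estimated correlation), with Gm2016 from 5.37 ± 5.88 FPKM (SD, n = 5) to 86.1 ± 80 (SD, n = 4) and Gm5662 from 11.9 ± 13.3 to 119 ± 91.4. Of the mzKO-down genes 116 of 1286 rose and 1, Myc (3.14 ± 1.01 to 0.918 ± 0.507), fell (0.833 with an estimated correlation), and Gm11517 rose by 5.85. Of the activated genes 132 rose and none fell (0.833 with an estimated correlation). The mzKO-up genes (9 up and 4 down, 0.833 with an estimated correlation) included BB287469 (7.87 ± 9.46 to 59.8 ± 48.9) as a rise and Dcun1d4 (2.53 ± 1.2 to 0.245 ± 0.0978) as a fall. Fbxo15 rose from 132 ± 34.4 to 779 ± 316 (pluripotency list, 0.209), Dppa3 from 151 ± 56.4 to 729 ± 401 (oocyte list, 0.782), Hand1 from 0.0405 ± 0.0587 to 2.11 ± 1.3 (trophectoderm list, 0.26) and Gata4 from 0.159 ± 0.0924 to 6.21 ± 3.55 (primitive endoderm list, 0.402). Sycp3 (4.2 ± 1.89 to 74.7 ± 75.2) rose among germ cell genes (0.833 with an estimated correlation), and Ei24, a p53 target, from 5.07 ± 3.3 to 22.6 ± 5.74. Krt18 rose from 4.52 ± 5.05 to 20.7 ± 9.75 (2.44, adjusted p = 0.0274), but with the replicate number as a block this was 2.03 with an adjusted p of 0.0533. Ribosomal proteins (0.985 with an estimated correlation, and 0.161 with the block) and fibroblast genes (0.828 with an estimated correlation) were called as lists with 0 members called.

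With Obox5, tested against the same GFP libraries, Guca1a rose to 219 ± 133 FPKM (SD, n = 4; 6.63, adjusted p = 3.7e-08), Trim43a to 87.9 ± 23.4 (6.26), Pemt to 186 ± 92, Bex6 to 22.1 ± 8.61, Ninj2 to 24.2 ± 6.92, Chit1 to 25.3 ± 18.3, Fmo1 to 15.4 ± 9.07, Crxos to 17.3 ± 10.1 and Aqp9 to 17 ± 8.66. Bnip3, a mitophagy gene, rose from 5.09 ± 4.22 to 57.3 ± 17.3. Of the 2-cell genes 6 of 33 rose (1.00 above all genes, adjusted p = 2.05e-09, and 0.673 with an estimated correlation), with Arg2 from 1.63 ± 1.45 to 20.8 ± 11.4 and Sp110 from 0.317 ± 0.288 to 11.5 ± 7.77. Dppa3 rose to 577 ± 161, Fbxo15 to 739 ± 244, Klf17 to 5.87 ± 1.34, Gata4 to 4.23 ± 3.04 and Ei24 to 22.9 ± 11.8. Brdt rose to 3.02 ± 2.21 with the germ cell list (0.733 with an estimated correlation).

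Of the mzKO-down genes 93 rose and none fell with Obox5 (adjusted p = 0.744 with an estimated correlation), Gm11517 by 6.31, and of the activated genes 105 rose and none fell (0.855). The mzKO-up genes had 4 up, with E330011O21Rik (0.357 ± 0.51 FPKM to 4.55 ± 1.84, SD, n = 5 and 4), and 1 down, Mc5r (-1.37), in Obox5 ESCs (0.855 with an estimated correlation). The p53 targets (0.733 with an estimated correlation), ribosomal proteins (0.988, and 0.101 with the replicate number as a block) and fibroblast genes (0.673) were called as lists. Trophectoderm genes were called only with the block (0.0185). In total 233 genes rose and 11 fell in Obox5 ESCs, 299 and 47 with the block, and 259 and 36 after scaling, which shifted the median of all genes by -0.11. Without Obox5oe replicate 4 the count was 132.

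Obox3 and Obox5 cells were also tested against each other. Obox3 was 8.27 higher (adjusted p = 0.0414) and Obox5 8.46 lower (-8.46, adjusted p = 0.00313) in Obox3 ESCs. OboxA9 was higher by 6.39 (190 ± 88.4 against 3.8 ± 7.51), and 4 other OboxA genes were called. Outside the family Gsc2, a goosecoid homeobox gene, was at 7.43 ± 5.45 FPKM (SD, n = 4) against 0.668 ± 0.349 (SD, n = 4; 2.11, adjusted p = 0.0279). The 2-cell genes stood 0.95 further above all genes with Obox3 (adjusted p = 3.81e-20, and 0.422 with an estimated correlation), with 0 of 33 called by limma, and p53 targets were lower (-0.32, 0.964 with an estimated correlation). In all 11 genes were higher and 1 lower (203 with an unadjusted p under 0.05), and 15 and 1 after scaling, which shifted the median by 0.136. With the replicate number as a block the 12 calls became 21 (20 up, 1 down), without Obox3oe replicate 1 they became 29, and with a pseudocount of 0.1 there were 0 in limma.

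**Figure D4:**
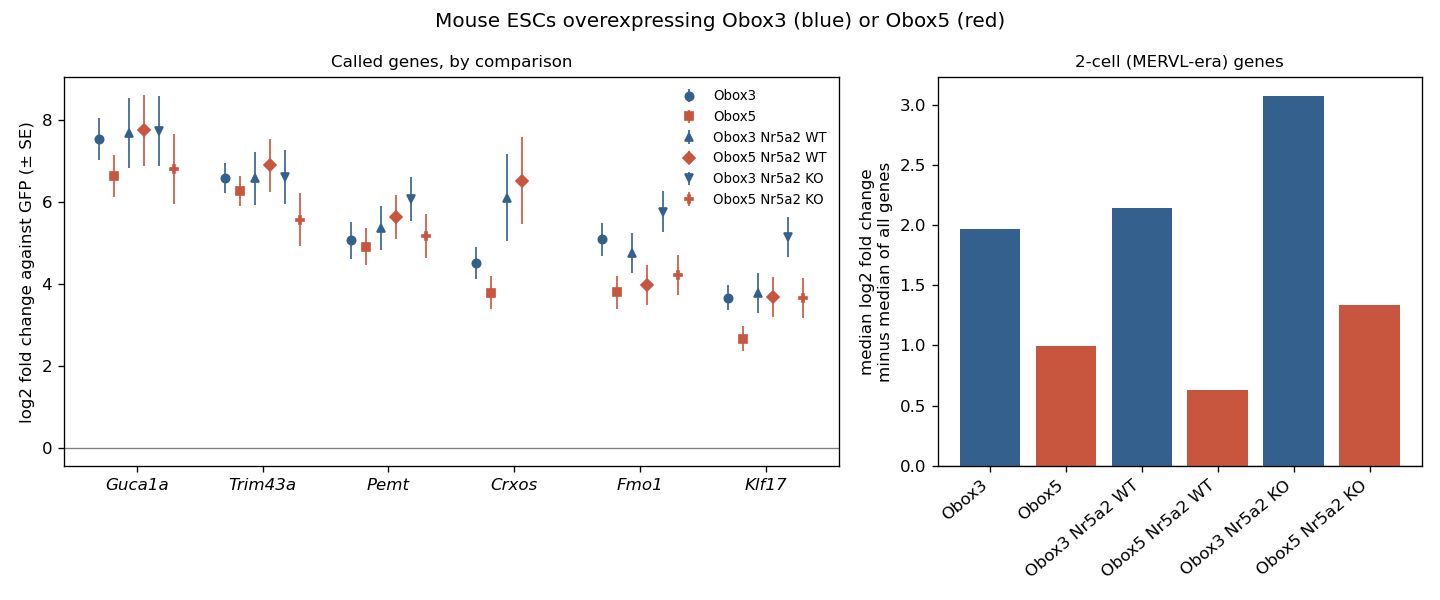
Left, log2 fold change ± SE of 6 genes on overexpression of Obox3 (blue) or Obox5 (red) in ESCs, where called. Right, median change of the 2-cell list minus that of all genes.

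The response recurred in the separate Nr5a2 table, with Obox3 at 243 ± 156 FPKM (SD, n = 2) against 0.0648 ± 0.0916 (SD, n = 2) and Obox5 at 541 ± 432 against 0.26 ± 0.204 in wild-type ESCs. Obox7 rose by 2.83 with Obox5. With Obox3, Guca1a rose from 0.947 ± 0.373 to 511 ± 462 (7.68, adjusted p = 0.00212), Trim43a from 0.0552 ± 0.0781 to 107 ± 56.4, Crxos from 0.0795 ± 0.0307 to 118 ± 132 and Pemt from 2.78 ± 0.653 to 163 ± 80.5. Oxr1 (12.8 ± 3.24 to 1.08 ± 0.0595), Fgfbp1 (20.2 ± 0.189 to 2.66 ± 2.24) and Rcbtb2 (8.3 ± 2.19 to 0.866 ± 0.128) fell. With Obox5, Guca1a rose to 435 ± 194, Trim43a to 125 ± 23.8, Crxos to 137 ± 137 and Pemt to 185 ± 2.37, and Oxr1 fell to 1.36 ± 0.206. The 2-cell genes were 2.14 above all genes with Obox3 (adjusted p = 6.56e-41, and 0.155 with an estimated correlation) and 0.63 with Obox5 (2.71e-09, and 0.988), with 7 and 1 of 38 called.

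The mzKO-down genes had 29 members up with Obox3 (adjusted p = 0.944 with an estimated correlation) and 36 with Obox5 (0.988) in Nr5a2 wild-type ESCs, and none down, their own median with Obox3 turning from -0.268 to 0.207 under scaling. Genes raised by Obox3 in both tables numbered 76 against 2.49 under independence, and 62 against 1.54 for Obox5. Counts were 90 up and 20 down for Obox3, and 262 and 22 after scaling, which shifted the median by 0.447 (upward share 81.8% to 92.3%), and 76 and 2 for Obox5. Ribosomal proteins were 0.68 above all genes with Obox3 (0.762). For Obox3 the count was 53 without the GFP library replicate 1, 35 without replicate 2, 173 without Obox3OE replicate 1 and 26 without Obox3OE replicate 2. For Obox5 it was 42 without the GFP library replicate 1, 31 without replicate 2 and 45 without Obox5OE replicate 2.

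Nr5a2, an orphan nuclear receptor, was near 0 in all ESCs labelled Nr5a2 KO and at 2.3 ± 0.909 FPKM (SD, n = 2) in wild type with GFP (-1.70, adjusted p = 0.0209). Without it Obox3 and Obox5 still raised their leading genes. With Obox3 (1560 ± 1350 against 0.305 ± 0.318), Guca1a rose from 1.74 ± 1.2 to 580 ± 256 (SD, n = 2 each; 7.73, adjusted p = 0.000582), Trim43a from 2.31 ± 3.26 to 231 ± 27.5, Pemt from 5.44 ± 0.129 to 450 ± 175 and Fmo1 from 0.264 ± 0.373 to 66.5 ± 8.77. Fgfbp1 (9.18 ± 0.416 to 0.428 ± 0.605) and Gjb5 (24.1 ± 7.5 to 3.68 ± 0.743) fell. With Obox5 (2030 ± 248 against 0.0446 ± 0.0631), Guca1a rose to 394 ± 379, Trim43a to 117 ± 48.4, Pemt to 276 ± 218 and Pdgfrl from 3.2 ± 0.0791 to 123 ± 56. Obox1 (2.81), Obox2 (2.49) and Obox7 (4.58) also rose with Obox5.

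The 2-cell genes rose by 3.08 with Obox3 in the Nr5a2 KO cells (24 of 38 up, none down, adjusted p = 7.1e-43, and 0.139 with an estimated correlation) and by 1.36 with Obox5 (5 up, 5.2e-23, and 0.267). The mzKO-down genes had 109 up and 1 down with Obox3 (0.883) and 42 up with Obox5 (0.92). Counts were 387 up and 32 down for Obox3 and 109 and 1 for Obox5, and 157 genes rose with Obox3 here and in the first ESC table against 8.71 under independence (63 against 1.91 for Obox5). For Obox3 the count was 233 without the GFP library replicate 1, 201 without replicate 2 and 168 without Obox3OE replicate 2. For Obox5 it was 50 without the GFP library replicate 1, 52 without replicate 2 and 27 without Obox5OE replicate 2.

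Loss of Nr5a2 by itself, in GFP cells, went with higher Mir692-2 and Mir692-3 (18.7 ± 12.3 FPKM to 4200 ± 2880, SD, n = 2 each), Mir692-1 (0.316 ± 0.317 to 142 ± 102) and Ly6a, a surface antigen (0.559 ± 0.287 to 265 ± 248, 7.02, adjusted p = 0.0174). Crxos, chosen after its values were seen, rose too, from 0.0795 ± 0.0307 to 89.1 ± 25.4 (adjusted p = 0.0192), so it was high before any Obox was added. Ubd and Apoa2 were listed at 0 in both knockout libraries against 82.3 ± 41.5 and 40.9 ± 11.1, and Rpl29 (449 ± 82.5 to 11.6 ± 4.95, -5.21) and Bst2 (61 ± 12.8 to 1.32 ± 1.47, -4.88) fell. Germ cell genes were 0.57 above all genes (adjusted p = 0.000563, and 0.981 with an estimated correlation), and the fibroblast (0.513 with an estimated correlation), sperm (0.101) and early mesoderm and ectoderm (0.513) lists were called. Counts were 97 up and 143 down, and 188 and 124 after scaling, which shifted the median by 0.256 (upward share 40.4% to 60.3%). Without Nr5a2 KO GFP replicate 1 the count was 135 (91 up, 44 down), without replicate 2 it was 130 (37 up, 93 down), and without the wild-type GFP libraries replicate 1 and 2 it was 94 and 113.

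Few genes were called for a different Obox3 effect in Nr5a2 KO and wild-type cells (median SE 0.622), so equal effects are not shown. Pdgfrl rose more with Obox3 where Nr5a2 was lost, from 3.2 ± 0.0791 FPKM (SD, n = 2) to 209 ± 76.2 (difference of changes 6.02, adjusted p = 0.000191). Dock9 (1.42 ± 0.216 to 20.8 ± 2.58, 3.75) and Mgll, a lipase (1.65 ± 0.99 to 31.1 ± 5.22, 3.51), behaved alike. For Obox5, Pdgfrl (5.20, adjusted p = 0.00169) was the only gene. The 2-cell genes rose more without Nr5a2, by 0.73 relative to all genes for Obox3 (adjusted p = 0.00113, and 0.851 with an estimated correlation) and by 0.60 for Obox5 (0.974), each with 0 members called by limma. Ribosomal proteins differed by -0.81 for Obox3 (0.76). The cells without Nr5a2 also held more of the constructs, Obox3 at 2520 and 610 against 133 and 353, and Obox5 at 1850 and 2200 against 847 and 235.

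For the Obox3 difference between Nr5a2 KO and wild-type cells, 8 genes were up and 4 down (620 with an unadjusted p under 0.05), and 4 and 6 after scaling, which shifted the median by -0.534 (upward share 66.7% to 40%). For Obox5 the shift was -0.144 and a second gene, down, joined Pdgfrl (upward share 100% to 50%; 192 with an unadjusted p under 0.05). The Obox3 count was 1 without KO_GFP replicate 1, WT_GFP replicate 1, WT_GFP replicate 2 or WT_Obox3OE replicate 2, 2 without WT_Obox3OE replicate 1, 3 without KO_GFP replicate 2 and 4 without KO_Obox3OE replicate 2. The Obox5 count was 4 without KO_Obox5OE replicate 1 and 2 without either WT_Obox5OE library.

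Genes raised by Obox3 in ESCs were among those lost in mzKO embryos more often than independence would give. Guca1a is a shared gene at the early 2-cell stage, where 10 genes were shared against 0.386 under independence. At the late 2-cell stage 116 were shared against 35.5, and at the 4-cell time 101 against 35.7. In mKO embryos 27 were shared against 34.8, in early Obox-- embryos 4 against 0.29 and in late Obox-- embryos 2 against 0.842.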

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

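The test without the ESC libraries numbered 1 was chosen only after the result was seen. In groups of 4 to 10 libraries, 17 of 116 values had a library far from the others, where chance gives about 1 in 20 groups. Most lie in the ESC libraries numbered 1. The GFP library replicate 1 held Obox1 at 2.14 FPKM, Obox2 at 6.78, Obox3 at 37.2, Obox5 at 19.2 and Obox7 at 20, while the other GFP libraries were at most at 0.204, 0.0303, 0.0668, 0.403 and 0.0952. Obox3oe replicate 1 held Obox1 at 3.39, Obox2 at 15.3, Obox5 at 30 and Obox7 at 28.4, with 8260 detected genes against 9800 to 9870 in the others, and Obox5oe replicate 1 held Obox2 at 24, Obox3 at 99.5 and the lowest stress response mean (3.99 against 4.78 to 4.87, log2). RNA of other Obox constructs in these libraries is a candidate source, but it could not raise the 2-cell genes in Obox3 cells by itself: without the 3 libraries numbered 1 they were still 1.849 above all genes (1.453 to 2.145 without 1 more library). GFP replicate 3 held Obox4 at 13.5 against 0.55 to 2.38, and Obox3oe replicate 3 had the highest 2-cell mean (4.15 against 2.88 to 3.07).

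In late 2-cell embryos Obox--_L2C replicate 1 had the highest germ cell mean (3.32 against 2.68 to 2.77) and Siah1a at 4.25 FPKM against 1.06 to 1.14. Effects differed between groups by a test of the difference for 12 genes between Obox3 in Nr5a2 KO and wild-type cells, for 1 gene with Obox5, and for 263 genes between mzKO at the late and early 2-cell stages.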

How the results depend on the processing

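Crossed pairings and leaving out Rn45s or all libraries with a given number were chosen only after the results were seen. None of the 921 gene and 572 list results was called in the opposite direction (relative to all genes for lists) with the other pseudocount, under scaling or with an estimated correlation. The balance of rises and falls did turn: for arrested embryos without Rn45s (3635 up, 2953 down), siObox5 and siObox6 with the pseudocount, siObox5 with a block, Nr5a2 KO against wild type (188 up, 124 down) and the Obox3 difference under scaling, and without single libraries for the 4-cell time, late minus early mzKO, siObox5 and Nr5a2 KO. With a pseudocount of 0.1 the counts became 736 for mKO, 39 for late Obox--, 1 for siObox5, 0 for siObox4, 3 for siObox6, 0 for Obox3 against Obox5, 137 for Obox5 in Nr5a2 wild-type ESCs, 2 and 2 for the differences of the Obox3 and Obox5 effects by Nr5a2, and 12 for late minus early mzKO. Without a filter they were 0 for mKO, 39 for late Obox--, 0 for siObox7, 5 for siObox4, 19 for siObox6, 1 for siObox8 and 157 for Obox5 in ESCs. In the Nr5a2 libraries they were then 25 and 24 for Obox3 and Obox5 in wild type, 177 and 23 in KO cells, 108 for KO against wild type, and 2 and 0 for the differences. With scaling they were 4 for MII, 106 for early mzKO, 0 for mKO, 2 for siObox4, 1 for siObox8, 284 for Obox3 in Nr5a2 wild-type ESCs, 2 for the Obox5 difference and 120 for late minus early mzKO, and the place of Obox4OE was 0.716. On the compared groups alone, early mzKO gave 33 and late Obox-- 25.

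With the replicate number as a block the counts were 1 for siObox5, 2 for siObox4, 14 for siObox6 and 21 for Obox3 against Obox5. In ESCs 62 of 63 named genes and 63 of 66 lists kept their call, but there were 479 calls for Obox3 (329 shared with the 338) and 346 for Obox5, with more falls. Crossed pairings (r = -0.316 and -0.157) gave 8 calls for MII and 2355 for mKO. Leaving out Rn45s gave 5 for full-grown oocytes, 4 for MII and 152 for late minus early mzKO, and leaving out both 4-cell libraries numbered 3 gave 2048 (940 up, 1108 down).

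Leaving out 1 library at a time, where a lone library left in a group is assumed to vary like the other groups, gave 8 to 9 calls for full-grown oocytes, 5 to 8 for MII, 38 to 57 for early mzKO, 1321 to 1973 for late mzKO, 2129 to 3776 for the 4-cell time, 4645 to 6359 for arrested embryos and 15 to 2940 for mKO. It gave 41 to 53 for early and 43 to 132 for late Obox--, 2 to 4 for siObox12mix, 1 to 6 for siObox5, 0 to 1 for siObox7, 0 to 0 for siObox4, 3 to 49 for siObox6 and 0 to 7 for siObox8. In ESCs it gave 230 to 373 for Obox3, 132 to 329 for Obox5 and 8 to 29 between them. In the Nr5a2 libraries it gave 26 to 173 and 31 to 55 in wild type, 168 to 366 and 27 to 163 in KO cells, 94 to 135 for KO against wild type, and 1 to 12 and 1 to 4 for the differences. Late minus early mzKO ranged from 62 to 476.

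Counts moved by over 1.5 times in 63 of 146 such fits. Of 921 gene calls or non-calls, 843 held with the other pseudocount (49 lost, 29 gained) and 878 under scaling (43 lost). Of 572 list results, 527 held under scaling (29 lost, 16 gained) and 375 with an estimated correlation (197 lost). With 1 library left out, 4495 of 4928 gene results held (395 lost, 38 gained).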

Other observations

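Apart from the splits of libraries and the ESC genes in embryos, the tests in this part were chosen only after the results were seen. Genes that Obox3 raised in ESCs were examined as a list in embryos, after the rise of mzKO-down genes in ESCs was known but before the list's values were seen. They stood at -0.394 relative to all genes in early mzKO embryos (camera adjusted p = 1.32e-28, 0.075 with an estimated correlation, and 0.00696 with that after scaling), and at -0.039 (0.374) in late Obox-- embryos. In early Obox-- and late mzKO embryos their medians were -0.017 and -1.108 against 0.238 and 0.012 for all genes. Camera adjusted p was 0.075 and 0.207 with an estimated correlation, and 0.00696 and 0.0196 after scaling. No tie to the first wave of zygotic transcription is shown.

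In mzKO embryos at the 4-cell time 2-cell genes were 1.844 above all genes after scaling (1.239 to 2.296 without 1 library). Totals largely cancel here and are untested. Delay is a candidate. On a 1833-gene axis from wild-type 4-cell (-0.108 to 0.056) to late 2-cell embryos (0.87 to 1.133), mzKO libraries lay at 0.582 to 0.968. Wild-type MII oocytes lay at 1.238 and 1.245, so no earlier stage stands out. Stress genes argue against delay alone. Their mzKO mean was a median 0.494 above the highest wild-type stage (0.252 to 0.742 over libraries, 16 of 25 above). Loss of Obox and arrest stay confounded.

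In mKO embryos 53% of genes with an unadjusted p under 0.05 were lower after scaling, against 85.5% as deposited. Scaling centres the typical gene, so lower FPKM totals and a true broad fall cannot be told apart. The median SE of called falls went from 0.375 to 0.364. The mzKO-down genes were at -0.646 relative to other genes after scaling (-0.83 to -0.439 without 1 library), where totals cancel.

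For the 2-cell genes in Obox3 ESCs, reads shared between copies cannot be told apart from a true rise: 4 of 11 members outside multi-copy families were called, all 11 being above 0, and 4 of 6 in a set picked by hand after the values were seen. The rise recurred in the Nr5a2 wild-type libraries (2.139 above all genes).

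Other splits of the libraries were fitted. For late mzKO (2165 calls, highest other split 4), the 4-cell time (3440 and 68) and early Obox-- embryos (54 and 1), 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. For late Obox-- embryos 2 of 35 splits did (74 and 76), the other joining Obox--_L2C replicate 1 with the Obox+- libraries, so chance is not excluded. For Obox3 in ESCs 2 of 100 splits did (338 and 1139), for Obox5 2 of 100 (244 and 1442), and between them 1 of 35 (12 and 2), shares under 0.05, but over splits that ignore the pairing. The split with 1139 calls follows replicate numbers and that with 1442 in part, which shows a structure of the samples. Among splits parting as many same-numbered pairs, which are too few for a share under 0.05, 1 of 13 (highest other 20), 1 of 15 (0) and 1 of 8 (0) gave as many.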
